A study of Mus musculus with 830 samples.

How the data were processed

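Single cells from the endoderm and gut of mouse embryos (cross C57BL/6XC3H) were profiled with Smart-seq3xpress, a plate-based full-length RNA-seq method. Per the labels' protocols, tissue was dissociated with trypsin, stained with an antibody to EpCAM (an epithelial surface protein) and sorted by flow cytometry, with dead cells excluded by DAPI. Whether cells were also gated on the reporter is not given in the sources used here, and the labels distinguish no batches. Each of the 830 deposited samples is 1 cell. The labels give 3 reporter genotypes. Ngn3Cre cells carry a Cre recombinase under Neurog3 control together with the Ai6 reporter, which marks cells and their descendants permanently. Ngn3GFP HZ cells carry 1 Neurog3 allele with GFP, and Ngn3GFP HM cells carry GFP on both alleles. Stages are given as somite numbers (15, 18, 21, 24 and 27).

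The deposited table of counts holds whole reads per gene and cell, not scaled, and the authors also deposited a table of TPM values for the same cells. The authors' TPM equals the counts divided by a gene length and rescaled to the same sum in each cell, since the largest log2 deviation of that ratio between cells was 1.4e-06. Per the submitters' processing notes, FastQC 0.11.9, Trimmomatic 0.39 and HISAT2 2.1.0 were used and the builds GRCm38 and mm10 are named. The read counter, the annotation, the use of strand and of unique molecular identifiers (UMIs), and any filter on cells are not given in the sources used here. In the median cell 57.2% of the nonzero counts were even, so a fragment may have been counted once per mate. No gene named as mitochondrial is listed. The tables list 26313 gene symbols, of which 4786 had no read in any cell and 25513 were found in GENCODE vM21, the GRCm38 annotation used here for positions. Reads of overlapping or near-identical genes cannot be separated in such counts.

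Totals ranged from 1400 to 2525083 reads per cell, with a median of 452597 reads and 7490 detected genes. No 2 cells had identical counts. 21 cells had under 2000 genes and 117 cells under 100000 reads. They stayed in the main analysis and were left out in alternatives. No doublet caller was run.

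The labels name no embryo, so cells were not used as replicates. Raw counts were summed over the cells of each genotype and stage, which gave 14 pools. The 11 pools of at least 10 cells entered the tests. The pools of Ngn3Cre at 18 somites (3 cells), HM at 27 somites (4 cells) and HZ at 15 somites (5 cells) were left out. An embryo has 1 somite number, so pools of different stages come from different embryos, and how many embryos made up a pool is not given. P-values therefore measure the spread of a difference between stages, which includes real changes of that difference with stage. Genotype contrasts (HM against HZ, Ngn3Cre against HZ) were fitted with genotype and stage as factors. HM and HZ shared 3 stages (18, 21 and 24 somites), and Ngn3Cre and HZ also 3 (21, 24 and 27). The HM pool of 15 somites was alone at its stage. It entered the means, filter and scaling, but with stage as a factor it carried no weight in these contrasts. A stage trend was fitted with genotype and somite number, as a slope per somite. A difference in slope between HM and HZ was fitted on their 8 pools. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts, with TMM scaling, edgeR's default filter on low counts and Benjamini-Hochberg adjustment at 0.05. Levels are CPM (reads of a gene over all reads of the pool, in the usual unit, with TMM scaling) computed here, as mean ± SD over the pools of a genotype; levels of single pools without scaling are named as such. The means cover HM pools of 15 to 24 somites, HZ pools of 18 to 27 and Ngn3Cre pools of 21 to 27. Means set side by side thus mix stage with genotype, while the fitted log2 fold changes hold stage as a factor. The SE of a log2 fold change is its size divided by the square root of the test's F statistic.

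Before the data were examined, 26 gene lists, 15 sets of cell type markers, the alternatives and the rule for naming genes were fixed. The rule takes, per comparison, the 8 largest rises and 8 largest falls past the threshold with a mean of at least 20 CPM in the higher group. It adds up to 4 members of each list with the smallest p, and 12 landmark genes. Some genes that this rule names are not reported here, though they stayed in every fit and list, and the tests of spilled reads, first run with 1 of them and then with 7 genes of the largest falls in HM, were replaced after their values were seen by tests on genes chosen without HM cells. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the 26 lists. A further planned test, limma's fry, asks whether a list's own genes change, without comparing them with other genes. A list's count "adjusted over the list alone" uses only its own members.

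Cells were clustered with scanpy 1.11.5 on log CPM, using 2000 variable genes, 20 principal components, 15 neighbours and the Leiden method at resolution 1.0. Shares between genotypes come from a clustering that left out the 329 genes called in either genotype contrast. Its clusters were still named with all markers, called genes among them. Pools restricted to or without certain clusters used the clustering on all genes. Pools without clusters with endocrine markers thus also lacked a pancreatic progenitor-like cluster of 48 cells, in which 3 endocrine markers were detected. A cluster was given a name only where at least 3 markers of a class were detected and at least 1 of them was among its 10 leading genes by fold. These limits were set after the data were seen. Endocrine progenitor, alpha, beta, delta and epsilon or enteroendocrine markers were joined as 1 endocrine-like class. The share of cells with a gene counts cells at 10 CPM or more, with an exact 95% binomial interval (Clopper-Pearson). Such intervals, and the floor of 3 counts used where a group had none, cover counting error only, since PCR copies are not independent molecules.

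The test was checked on simulated counts with the pools' own means and spreads, in which 200 genes were changed. These were drawn only from genes above a minimum mean CPM, so recovery at lower levels is not known. Recovery is a share over genes of differing spread and does not hold for each gene. For HM against HZ (17766 genes), 22% of genes changed by a log2 of 1 were recovered, 84% at 2, 90% at 3 and 98% at 4, and 20 of the 167 calls were unchanged genes. For Ngn3Cre against HZ (17708 genes) these were 28%, 78%, 98% and 100%, with 32 of 184 calls unchanged. The share of false calls was thus above the nominal 0.05 in both. For the stage trend (15873 genes, change over the whole stage range) they were 0%, 28%, 56% and 74%, with 1 false call. For the difference in slope (15545 genes) no changed gene was recovered. There each size was set over a range wider than the HM stages, so the change of slope across those stages was smaller than the size named.

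The alternatives were DESeq2 (1.42.0) as a test and as scaling, no filter on low counts, other limits on cells and pools, means of log2(CPM + 1) or log2(TPM + 1) over cells with limma, 10 cells drawn per pool, each pool left out in turn, other designs, other clusterings and other thresholds for shares. Library totals without scaling factors, and pools restricted by depth, stage or cell class, were added after the data were seen.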

Results

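Transcriptomes of 830 sorted endoderm and gut cells from mouse embryos of 15 to 27 somites were compared between 3 reporters of Neurog3 (also called Ngn3), the basic helix-loop-helix factor that starts endocrine differentiation in the pancreas and gut. The series traces cell lineages of the early endoderm. The Cre lineage reporter (Ngn3Cre) gave 333 cells, the heterozygous GFP reporter (HZ) 326 cells and the homozygous GFP reporter (HM) 171 cells. Median depth was 465918 reads per cell for Ngn3Cre, 378157 for HZ and 626967 for HM. Pools of the cells of a genotype and stage held 8299225 to 70763553 reads among the 11 pools tested.

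Neurog3 itself (chromosome 10, 62133090 to 62134763, plus strand, GRCm38) was lower in HM than in HZ. It averaged 9.01 ± 2.04 CPM in HM (SD, n = 4 pools) and 108 ± 29.8 CPM in HZ (SD, n = 4 pools), a log2 fold change of -3.69 ± 0.44 (SE; edgeR adjusted p = 0.00336). The highest HM pool (10.8 CPM) lay below the lowest HZ pool (77.8 CPM). Without the cells of clusters with endocrine or neural markers the log2 fold change was -0.90 and did not pass, but Neurog3 is itself a marker of those clusters, so this filter depends on the gene. The filter also left out a pancreatic progenitor-like cluster of 48 cells (17 HM and 30 HZ). In pancreatic progenitor-like cells, from a clustering without the called genes, Neurog3 averaged 11.2 CPM in HM and 137 CPM in HZ. Reads remained in HM, and at 24 somites 42.5% of HM cells had Neurog3 at 10 CPM or more (34 of 80 cells, 31.5% to 54.1%), beside 54.1% of HZ cells (46 of 85, 43.0% to 65.0%). At 21 somites the shares were 16.7% (9 of 54, 7.92% to 29.3%) and 53.7% (80 of 149), and at 18 somites 35.3% (6 of 17) and 34.4% (21 of 61). At a threshold of 50 CPM no HM cell of 24 somites remained, which allows a share of up to 3.75%, against 30.6% of HZ cells, and at 21 somites 1 of 54 HM cells (1.85%) remained, against 42.3% of HZ cells. With each cell thinned to 100000 reads, where 10 CPM is 1 read, the shares at 24 somites were 49.3% in HM and 60.6% in HZ, without the 7 HM and 14 HZ cells of lower depth. At 21 somites they were 30.6% in HM (11 of 36) and 61.4% in HZ (81 of 132), without the 18 HM and 17 HZ cells of lower depth. In the 20 hepatic-like cells, which should lack the gene, the share at 10 CPM was 10.0% (1.23% to 31.7%), at a median of 1162435 reads per cell.

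**Figure D1:**
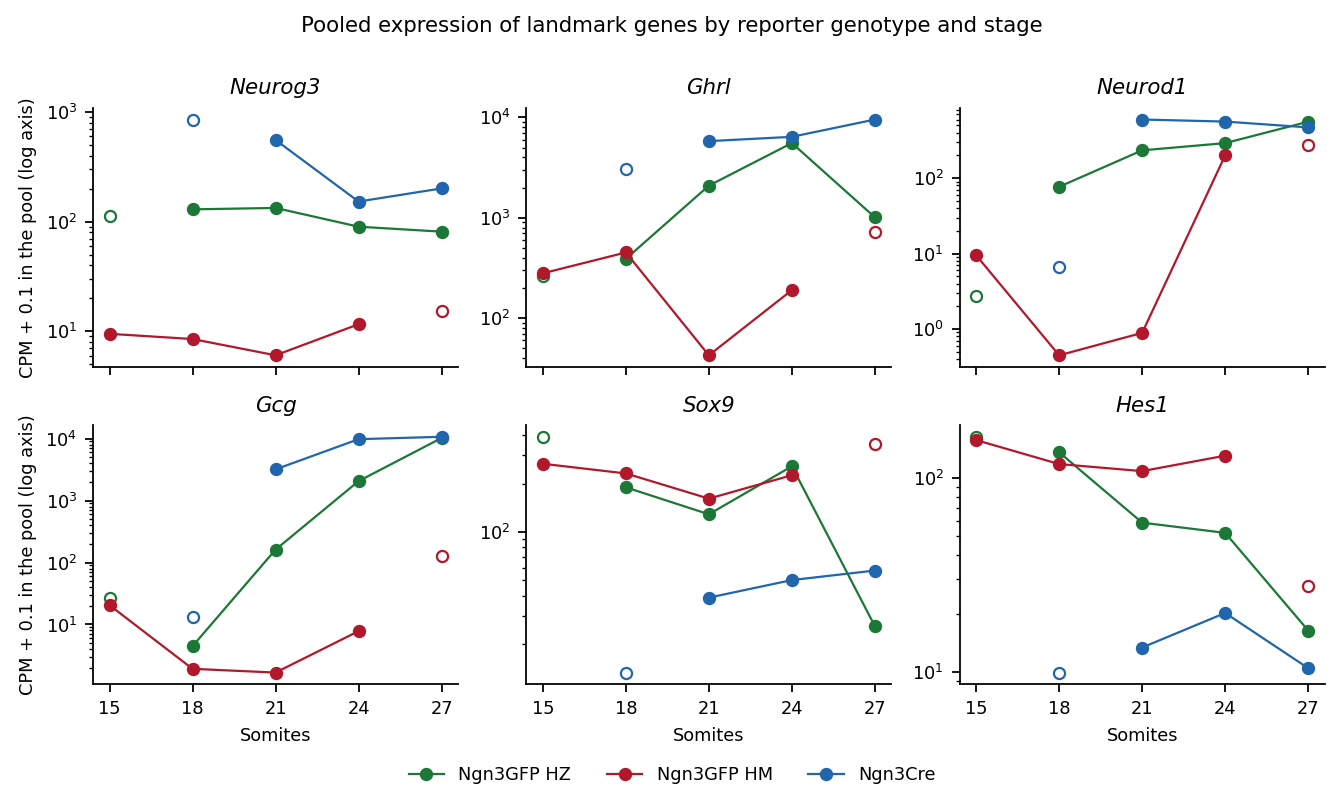
Expression of 6 landmark genes in each pool, as CPM with 0.1 added on a log axis, against somite number. Filled points are pools of at least 10 cells, open points smaller pools that entered no test, and lines join pools of 1 genotype. Neurog3 lay lower in every HM pool than in any HZ pool tested.

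The comparison of HM with HZ asks what changes when both Neurog3 alleles carry GFP. Genes of endocrine cells were lower in HM. In edgeR 254 of 18420 tested genes fell and 17 rose. DESeq2 called 1072 lower and 314 higher, while limma on means over cells called more higher than lower genes, 110 and 61 on log2 CPM and 74 and 36 on log2 TPM, so the balance of directions depended on the method. Among genes with at least 20 CPM in the higher group, the largest fall was that of Gpr119, a lipid-sensing receptor of endocrine cells, at 0.180 ± 0.235 CPM in HM and 48.2 ± 27.2 CPM in HZ (log2 fold change -9.38 ± 0.47, adjusted p = 3.25e-05). Pax4, a transcription factor of islet cell fate, fell by 7.98 ± 0.57 on the log2 scale (adjusted p = 0.000269). Pou3f4, Lrrtm3, Dbpht2, Pcsk2 and Sphkap were also among the largest falls, with log2 fold changes from -8.69 to -7.63. Each of these 7 genes was lower in HM at all 3 shared stages, though for Pou3f4 at 18 somites this rests on 0 reads in HM and 6 in HZ.

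By list, 10 of 24 endocrine transcription factors fell and none rose, with Pax6 (-6.90 ± 0.56) beside Pax4. Adjusted over the list alone, 19 fell and 1 rose, Sox11 (log2 fold change 0.53, adjusted p over all genes 0.346), a gene named after its values were seen. Of 13 hormones tested, 4 fell, namely Cck, Pyy, Ppy and Iapp, and 9 fell adjusted over the list alone. Pyy averaged 31.3 ± 33.5 CPM in HM and 1415 ± 1375 CPM in HZ, and its call was lost in 7 of the 11 fits with a pool left out, beside 3 for Cck and 1 for Ppy. Of 22 genes of hormone processing and granules, 12 fell, among them the granule proteins Resp18 (-9.55 ± 0.82) and Ptprn (-4.79 ± 0.43), the vesicle fusion regulator Cplx2 (-3.23 ± 0.31) and the prohormone convertase Pcsk1 (-4.97 ± 0.54). 21 fell adjusted over the list alone. These 3 lists were lower by camera (adjusted p = 1.88e-12, 1.27e-06 and 4.37e-16). With an estimated correlation their adjusted p by camera was 0.408, 0.176 and 0.354, and no list passed. By fry their adjusted p was 0.0249, 0.00686 and 0.0137, and of the other lists only Hedgehog genes passed (0.0137).

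Several landmarks of the endocrine lineage had large but uneven differences that did not pass. Gcg, the glucagon gene, averaged 8.20 ± 9.56 CPM in HM and 2994 ± 4638 CPM in HZ (log2 fold change -6.54 ± 1.57, adjusted p = 0.0895). The HZ mean came mostly from the pool of 27 somites (10233 CPM without scaling), a stage with no HM pool tested. At 18, 21 and 24 somites, without scaling, HZ had 4.36, 161 and 2058 CPM of Gcg, and HM 1.82, 1.57 and 7.70 CPM. Neurod1 (-4.13 ± 1.62, adjusted p = 0.298), Fev (-4.79 ± 1.90, 0.303), Ghrl (-3.62 ± 1.17, 0.208) and Chga (-2.86 ± 0.94, 0.216) did not pass either. With a pool left out, values ranged from -8.06 to -5.14 for Gcg, -8.34 to -2.53 for Neurod1, -6.64 to -2.30 for Fev, -4.85 to -2.21 for Ghrl and -4.10 to -1.59 for Chga, and Neurod1 passed in 1 and each of the other 4 in 2 of the 11 fits. Neurod1 reached 189 CPM in the HM pool of 24 somites, while the lowest HM pool had 0.363 CPM. The cell cycle inhibitors Cdkn1a (144 ± 12.2 against 568 ± 125 CPM, adjusted p = 0.0066) and Btg2 (50.1 ± 37.4 against 401 ± 81.4 CPM, adjusted p = 0.0114), fell, and Btg2 was also the 1 gene of the dissociation stress list to fall. The Notch ligands Dll3 and Dll4 fell by 4.68 ± 0.83 and 3.59 ± 0.65 on the log2 scale, while the other 19 genes of the Notch list did not pass. These calls were lost in 4 (Dll3) and 7 (Dll4) of the 11 fits with a pool left out. Without clusters with endocrine or neural markers Dll4 turned to 0.070. The Notch list had a positive median (0.10), a negative mean (-0.82) and a direction of down by camera (adjusted p = 0.275).

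Among progenitor genes, Prox1 fell (55.7 ± 14.4 against 170 ± 61.0 CPM, adjusted p = 0.0226, a call lost in 5 of the 11 fits with a pool left out) and the other 18 genes of the pancreatic progenitor list did not pass. Pdx1 (34.8 ± 11.6 CPM in HM, 22.1 ± 10.3 in HZ), Sox9 (228 ± 49.9 and 149 ± 96.4), Hes1 (132 ± 25.0 and 66.0 ± 52.2), Epcam (648 ± 134 and 468 ± 189) and Ptf1a (1.59 ± 1.77 and 0.743 ± 1.42) did not pass (adjusted p = 0.562, 0.743, 0.291, 0.676 and 0.714). The rises included Fxyd2, a subunit of the sodium pump (2.61 ± 0.52, adjusted p = 0.0439), the ceramide synthase Cers4 (1.91 ± 0.34), the matrix protein Cyr61 (1.71 ± 0.30), Klf6 (1.40 ± 0.27) and the adaptor Gab1 (1.34 ± 0.24). Slc39a8, Pla2g7 and Car14 rose by between 1.13 and 1.14. The calls of these 7 genes other than Fxyd2 were lost in 5 to 8 of the 11 fits with a pool left out. Fxyd2 had no read in 1 HM pool and up to 84.2 CPM in another, and its call was kept without Ngn3Cre at 21 or 24 somites but lost without any other single pool, at values of 2.20 to 3.03. With 10 cells drawn per pool Fxyd2 turned to -0.13.

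Other lists moved with the genotype by camera. All 20 S phase genes had positive log2 fold changes (median 0.53), though none passed alone and 5 rose adjusted over the list alone (camera adjusted p = 1.06e-05). The Hedgehog pathway was higher (adjusted p = 0.0153) with 1 gene past the threshold, the signal transducer Smo (0.93 ± 0.18, adjusted p = 0.0379), whose call was lost in 10 of the 11 fits with a pool left out, and Shh at 52.6 ± 12.4 against 15.1 ± 9.34 CPM (adjusted p = 0.0561). Epithelial adhesion, hepatic and biliary genes were higher (adjusted p = 0.0133, 0.0143 and 0.0483) with no gene past the threshold. With an estimated correlation the adjusted p of these 5 lists was 0.576, 0.354, 0.631, 0.631 and 0.468. Markers of other cell types moved as well: mesenchyme and neural or neural crest genes were lower (adjusted p = 0.000623 and 0.0219, or 0.494 and 0.609 with an estimated correlation). Foxd3, a neural crest factor, had no read in the HM pools and 3.38 ± 2.96 CPM in HZ, at least 124-fold lower against a floor of 3 counts over the HM pools. Its call was lost in 6 of the 11 fits with a pool left out, and its log2 fold change was 0.0086 with 10 cells drawn per pool. The lists of G2 and M phase, cell cycle inhibitors, Notch, pancreatic progenitor, mesenchymal transition, intestine, anterior foregut, Wnt, retinoic acid, p53, dissociation stress, unfolded protein, blood, endothelium, notochord and sex-linked genes did not pass by camera.

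The fit had 4 residual degrees of freedom, and the number of falls depended on single pools: it was 88 without HZ at 21 somites, 127 without HM at 21, 130 without HZ at 24 and 152 without Ngn3Cre at 21. The 17 rises became 0 without HM at 21 or HZ at 24 somites, 1 without HZ at 21, 5 without HM at 24, 9 without Ngn3Cre at 27, 10 without Ngn3Cre at 21, 26 without HM at 18 and 31 without HZ at 18. Without the cells of clusters with endocrine or neural markers, 7 genes fell and 0 rose in edgeR, with 692 at an unadjusted p under 0.05, and no other tool was run on these cells. Of the 271 genes called with all cells, 2 remained, among them Slc38a5 (log2 fold change -3.21, adjusted p = 0.00128). The 5 new falls were collagens and a matrix gene of mesenchyme (Col3a1 -7.69, Col1a1 -3.66, Lum -10.6) and neuronal genes (Tubb3 -5.05, Nefm -4.62). This fit had 2 residual degrees of freedom in place of 4, and it also lacked a pancreatic progenitor-like cluster of 48 cells. With the clusters to leave out taken instead from the clustering without the called genes, 250 of the 254 fallen genes were still lower in HM. Their median log2 difference was -0.95 in place of -2.04. Those genes were chosen for falls in pools that include these cells, so that many stay lower is expected.

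**Figure D2:**
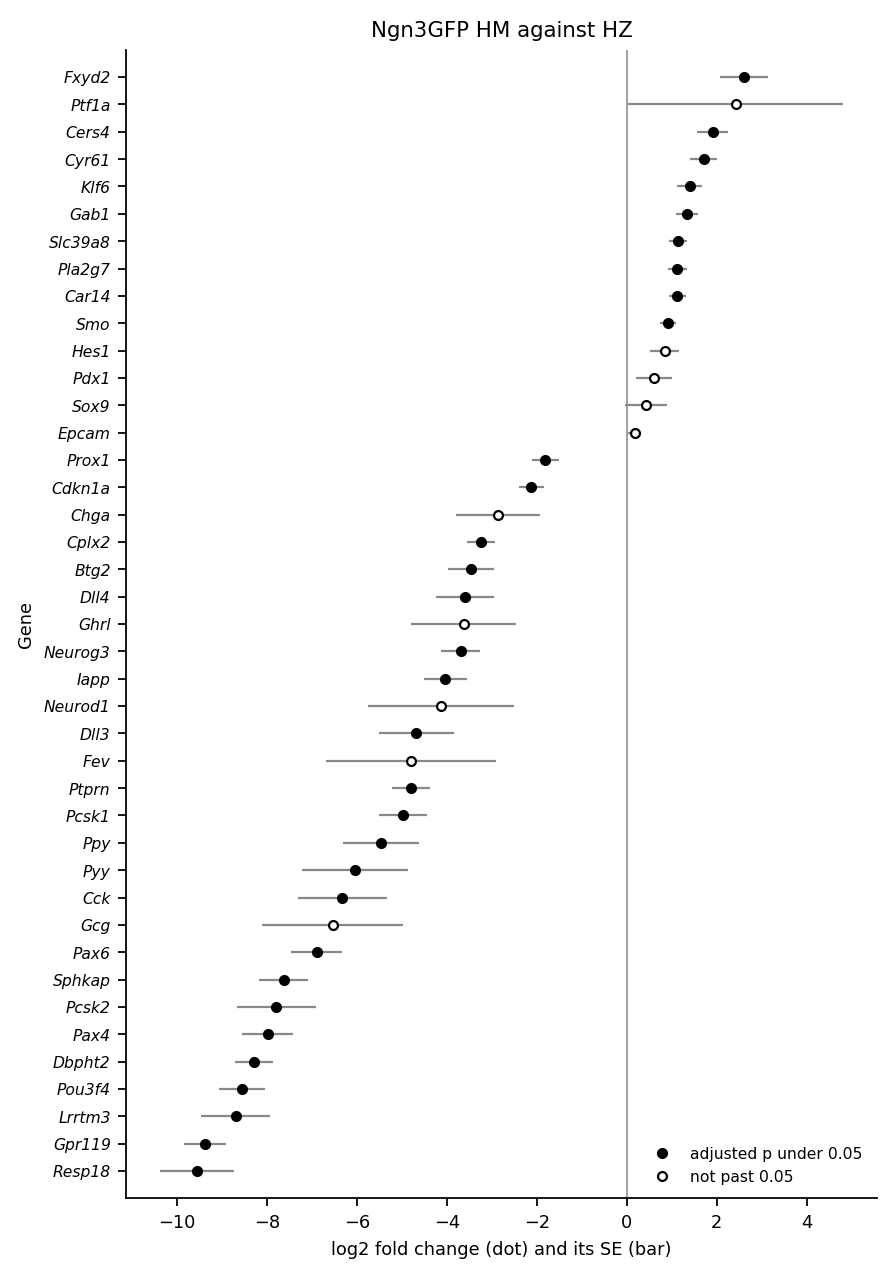
Log2 fold change of HM against HZ (x axis) for the named genes (y axis), as dots with bars for the SE from edgeR over 11 pools. Filled dots passed an adjusted p of 0.05. Among the genes shown, the falls reach -9.55 (Resp18), while the highest rise is 2.61 (Fxyd2). Foxd3, with no read in the HM pools, is not shown.

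Clustering of the cells without the called genes gave 13 clusters, and cells of endocrine-like clusters were nearly missing from HM. The names of the clusters still rest on markers that include called genes such as Pax4 and Pcsk2, so these shares are not independent of the calls. The endocrine-like class (354 cells) joined 4 clusters, whose 10 leading genes included Fev, Pax4 and Pou3f4 in 1, Neurog3 in another, Gcg and Pcsk2 in 1 of 121 cells, and Acsl1, Car3 and Ghrl in 1 of 28 cells. It held 2 of 134 HM cells at 21 and 24 somites together (1.49%, 0.181% to 5.29%). In HZ it held 105 of 234 (44.9%, 38.4% to 51.5%), and in Ngn3Cre 177 of 261 (67.8%, 61.8% to 73.4%). The 2 HM cells lay in different clusters of that class. In HZ the share was 14.8% at 18 somites (9 of 61), 42.3% at 21 (63 of 149), 49.4% at 24 (42 of 85) and 50.0% at 27 (13 of 26). The class was smaller under TPM values (23.9% in HZ, 57.9% in Ngn3Cre).

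Pancreatic progenitor-like cells, with Pdx1, Sox9, Nkx6-2 and Mnx1, made up 33 of 134 HM cells at 21 and 24 somites (24.6%, 17.6% to 32.8%), 34 of 234 HZ cells (14.5%, 10.3% to 19.7%) and 9 of 261 Ngn3Cre cells (3.45%, 1.59% to 6.44%). Neural or neural crest-like cells, with Neurog2 and Tlx2 among their leading genes, made up 12.6% of Ngn3Cre cells (33 of 261, 8.87% to 17.3%), 5.13% of HZ cells (12 of 234) and 3.73% of HM cells (5 of 134). Hepatic-like cells, with Apoa1, Afp and Fgb, made up 6.72% of HM cells (9 of 134), 1.28% of HZ cells (3 of 234) and 0 of 261 Ngn3Cre cells, which allows a share of up to 1.15%. At 18 somites they were 1 of 17 HM and 7 of 61 HZ cells, and over all stages 10 HM and 10 HZ cells. Of the 5 unnamed clusters, 1 of 72 cells with Osr2 and Sycn among its leading genes held 48 HM and 24 HZ cells, and 1 of 59 cells at a median of 48886 reads, with Gcg and Slc38a5 detected, held 33 Ngn3Cre, 2 HM and 24 HZ cells. The shares of a genotype add up to all its cells, so where endocrine-like cells are few, as in HM, the shares of other classes rise. A higher share in HM therefore need not mean that a class was more frequent among the remaining cells. No test of these shares over pools was run. Cells were sorted after an EpCAM stain, and shares of sorted cells are not shares of the tissue.

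**Figure D3:**
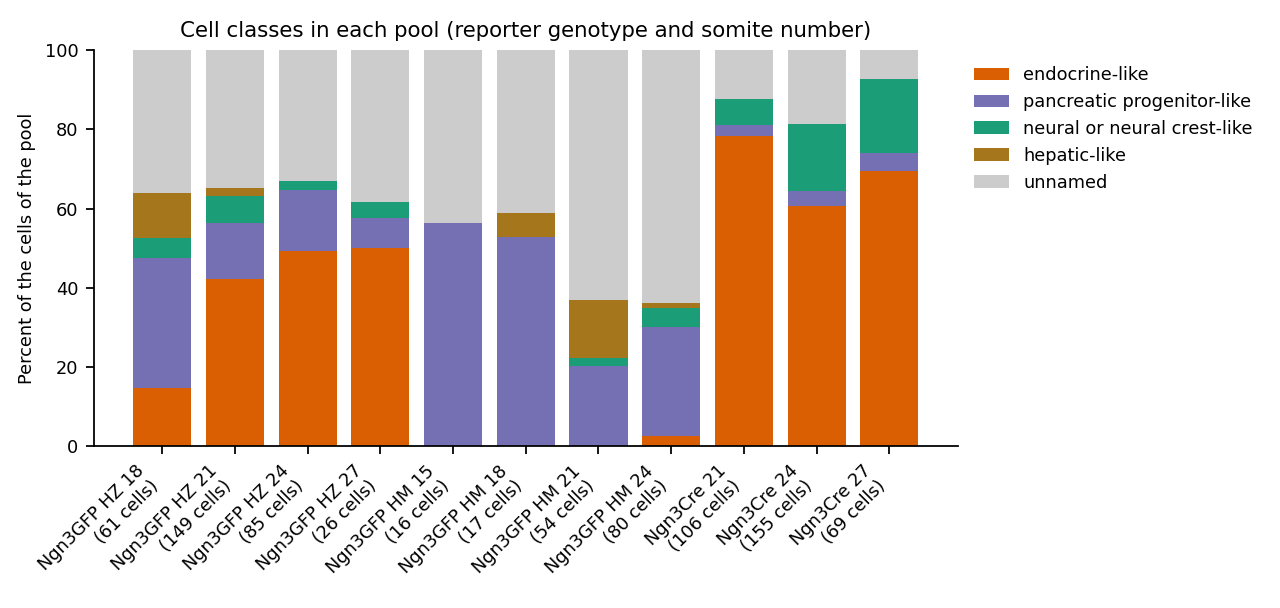
Percent of the cells of each pool (y axis) in the classes named from fixed markers, for the 11 pools of at least 10 cells. The endocrine-like part is 14.8% to 50.0% in HZ, 0% to 2.5% in HM and 60.6% to 78.3% in Ngn3Cre.

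At 24 somites, Neurod1 was at 10 CPM or more in 23.8% of HM cells, 69.4% of HZ cells and 89.7% of Ngn3Cre cells, Gcg in 27.5%, 72.9% and 96.1%, and Ghrl in 66.25%, 97.6% and 98.1%. Neurog3 was so in 35.5% of Ngn3Cre cells (28.0% to 43.6%). In hepatic-like cells of all stages the shares of Neurod1 and Gcg were each 5.00% (0.127% to 24.9%), and that of Ghrl was 30.0%. In neural or neural crest-like cells of all stages the share of Ghrl was 77.9%. In neural or neural crest-like cells of all stages Gcg was so in 95.7% of 46 Ngn3Cre, 66.7% of 6 HM and 31.25% of 16 HZ cells. At 24 somites and 50 CPM, Gcg remained in 6.25% of HM, 38.8% of HZ and 84.5% of Ngn3Cre cells. Ghrl then remained in 15.0%, 84.7% and 91.0%, and Neurod1 in 15.0%, 62.4% and 83.2%.

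The comparison of Ngn3Cre with HZ sets sorted cells of a lineage reporter against sorted cells of the GFP reporter, and whether the cells carried the mark is not given. Genes of G2 and M phase lay lower in Ngn3Cre by camera, with 6 of 22 past the threshold alone. That list did not pass by camera with an estimated correlation (adjusted p = 0.541). 61 genes fell and 1 rose. The gene that rose was Aplp1, of the amyloid precursor family (235 ± 10.7 CPM in Ngn3Cre, n = 3 pools, against 93.6 ± 36.9 CPM in HZ, n = 4 pools; log2 fold change 1.19 ± 0.19, adjusted p = 0.0417). Among the largest falls were the galectin Lgals2 (-6.36 ± 0.75), Tdh (-4.21 ± 0.53), the intestinal factor Cdx2 (-3.94 ± 0.49), Tspan8 (-2.84 ± 0.47), the spindle gene Aspm (-2.71 ± 0.42), Lpar3 (-2.70 ± 0.37) and Gpc6 (-2.54 ± 0.31), with adjusted p between 0.0185 and 0.0452. Shh, a ligand of the early gut epithelium, fell by 3.33 ± 0.30 on the log2 scale (1.34 ± 1.05 against 15.1 ± 9.34 CPM, adjusted p = 0.00766), and the matrix metalloproteinase Mmp14 fell by 1.99 ± 0.23. Each of these genes differed in the same direction at all 3 shared stages. In pools of endocrine-like cells alone Cdx2 turned to 0.51 and was not called. Calls were lost in 6 (Aplp1), 8 (Tspan8), 6 (Aspm) and 4 (Lpar3) of the 11 fits with a pool left out, and in 1 or 2 for the other 6 falls named here.

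All 22 genes of G2 and M phase had negative log2 fold changes (median -2.01). In pools of endocrine-like cells alone the median was -0.39, with 20 of 22 negative, so the make-up of the pools may carry a part of this. With all cells 6 of the 22 fell, among them Aurkb (12.3 ± 3.95 against 59.5 ± 22.6 CPM), Cenpe (12.0 ± 3.89 against 66.6 ± 23.0), Bub1b (13.8 ± 3.06 against 47.2 ± 2.98) and Nusap1 (19.2 ± 6.82 against 111 ± 43.8), and 22 fell adjusted over the list alone. Calls were lost in 4 (Bub1b and Nusap1), 3 (Cenpe) and 2 (Aurkb) of the 11 fits with a pool left out. The list was lower by camera (adjusted p = 7.27e-20, or 0.541 with an estimated correlation). S phase genes were lower too (adjusted p = 3.10e-06, or 0.541), with none past the threshold and 11 adjusted over the list alone. The endocrine lists lay higher in Ngn3Cre by camera, with no gene past the threshold: endocrine transcription factors (adjusted p = 0.00209), hormones (0.000128) and hormone processing (3.73e-06). With an estimated correlation their adjusted p was 0.620, 0.331 and 0.541. Examples were Ppy at 38.5 ± 18.0 against 4.31 ± 2.92 CPM and Cpe at 344 ± 8.96 against 119 ± 57.4 CPM.

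The Hedgehog (adjusted p = 0.00362), epithelial adhesion (0.0141), mesenchymal transition (0.0158), intestinal (0.0337) and Wnt (0.0473) lists were lower and the unfolded protein response list higher (0.00156). With an estimated correlation these adjusted p were 0.331, 0.642, 0.541, 0.620, 0.541 and 0.541. By fry only the Hedgehog (adjusted p = 0.00485) and hormone lists (0.0481) passed. Shh was the 1 Hedgehog gene, Cdx2 the 1 intestinal gene, Mmp14 the 1 gene of mesenchymal transition and Tspan8 the 1 biliary gene to fall. The other 15 lists did not pass by camera, among them neural and neural crest genes, with a median of -0.17, a mean of 0.25 and a direction of up by camera (adjusted p = 0.345). Cell cycle inhibitors (median -0.03, mean -0.07) and notochord genes (-0.80, -0.68) were also up by camera, and sex-linked genes (0.06, 0.01) down, each with an adjusted p of 0.827.

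No landmark passed in this comparison. Neurog3 averaged 300 ± 223 CPM in Ngn3Cre (log2 fold change 1.43 ± 0.39, adjusted p = 0.174), Gcg 7675 ± 3914 CPM (2.80 ± 1.04, 0.345), Ghrl 7073 ± 1865 CPM (1.97 ± 0.84, 0.446), Chga 338 ± 28.3 CPM (1.71 ± 0.68, 0.3895) and Fev 91.8 ± 50.4 CPM (2.13 ± 1.15, 0.574). Neurod1 (0.40 ± 1.23), Hes1 (-1.57 ± 0.36), Sox9 (-1.11 ± 0.57), Pdx1 (-0.58 ± 0.41), Ptf1a (-1.02 ± 2.48) and Epcam (-0.11 ± 0.16) had adjusted p between 0.1097 and 0.963. Without the Ngn3Cre pool of 21 somites edgeR called 0 genes, with 976 at an unadjusted p under 0.05. The number of falls was 6 without HZ at 21, 17 without HM at 24, 99 without Ngn3Cre at 27, 101 without Ngn3Cre at 24 and 103 without HZ at 27 somites. The number of rises was 0 without Ngn3Cre at 21 or 27 or HZ at 21 or 27, 3 without Ngn3Cre at 24 or HM at 18, 4 without HZ at 24 and 11 without HM at 21. Restricted to endocrine-like cells, where HZ at 18 somites had too few cells for a pool, edgeR called 0 of 15402 genes, with 762 at an unadjusted p under 0.05. With all cells DESeq2 called 920 genes, and limma 0 on log2 CPM and 0 on log2 TPM.

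**Figure D4:**
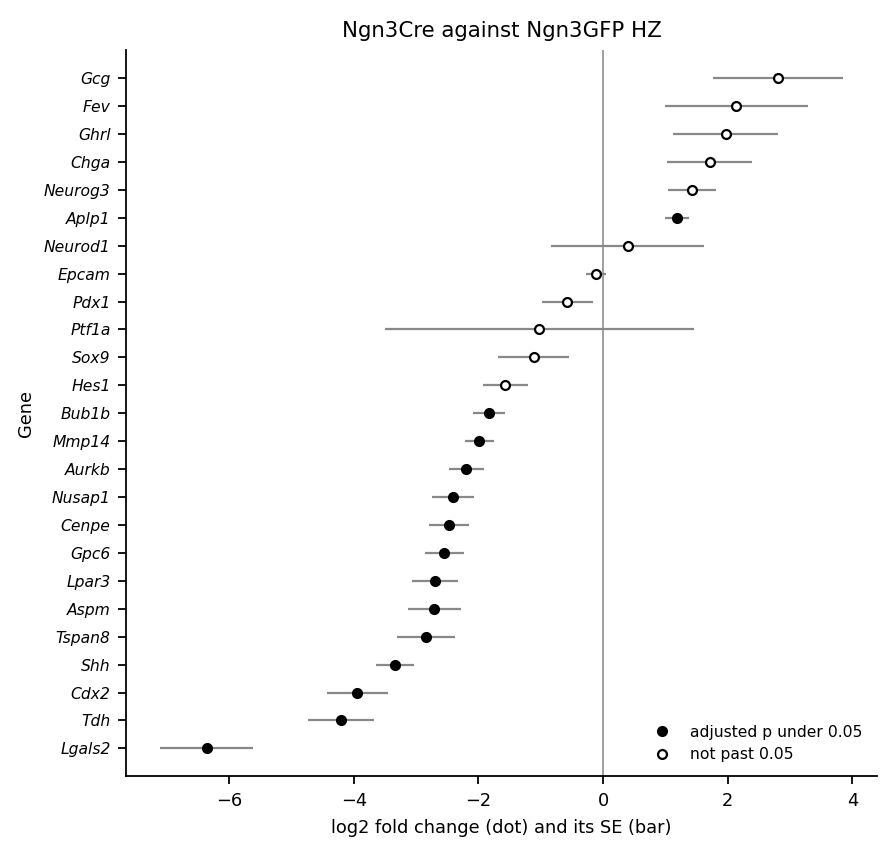
Log2 fold change of Ngn3Cre against HZ (x axis) for the named genes (y axis), as dots with bars for the SE from edgeR over 11 pools. Filled dots passed an adjusted p of 0.05. Aplp1 (1.19) is the only filled dot above 0, and the lowest is Lgals2 (-6.36).

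Across somite stages, adjusted for genotype, no gene passed in edgeR: 0 of 16478 genes were called, 1377 had an unadjusted p under 0.05, DESeq2 called 305, and limma 1 on log2 CPM and 1 on log2 TPM. Without Ngn3Cre at 24 or 27 somites edgeR called 1 and 2 genes. By list, posterior Hox and Cdx genes of the intestinal list were lower at later stages (all 16 negative, camera adjusted p = 1.20e-08, or 0.300 with an estimated correlation), with 7 past the threshold adjusted over the list alone. Examples were Hoxc6 (-0.41 ± 0.11 per somite, edgeR adjusted p = 0.334) and Hoxa7 (-0.36 ± 0.11, 0.364). Epithelial adhesion genes (adjusted p = 4.96e-08), notochord genes (0.000183), endothelial genes (0.00156) and Wnt genes (0.00474) were lower at later stages, and hormone processing genes higher (4.69e-05). With an estimated correlation the adjusted p of these 5 lists were 0.550, 0.300, 0.300, 0.529 and 0.550. By fry no list passed for the trend, with a smallest adjusted p of 0.185. Epcam had a slope of -0.12 ± 0.02 per somite (edgeR adjusted p = 0.260), the granule gene Scgn 0.54 ± 0.09 (0.204) and Ptprn 0.43 ± 0.11 (0.295). The other 20 lists did not pass by camera. Among these, camera's direction was down while the median or the mean slope was above 0 for pancreatic progenitor genes (-0.01, 0.10; adjusted p = 0.609), Notch genes (-0.0046, 0.0071; 0.623), mesenchymal transition genes (0.02, 0.04; 0.924) and sex-linked genes (-0.0085, 0.0096; 0.924).

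No landmark slope passed. Slopes were -0.16 ± 0.05 per somite for Hes1, -0.08 ± 0.04 for Neurog3, 0.35 ± 0.15 for Neurod1, 0.27 ± 0.26 for Gcg, 0.16 ± 0.10 for Chga, 0.37 ± 0.38 for Ptf1a and -0.18 ± 0.18 for Fev. Ghrl (0.0036 ± 0.12), Pdx1 (-0.01 ± 0.05) and Sox9 (-0.07 ± 0.07) were near 0. Without scaling, Gcg went from 4.36 CPM at 18 somites to 10233 CPM at 27 somites in HZ, and from 3187 CPM at 21 to 10698 CPM at 27 in Ngn3Cre, while the 4 HM pools of 15 to 24 somites had 1.57 to 20.4 CPM and the HM pool of 27 somites, with 4 cells, 127.5 CPM (225 reads). These are totals of single pools with no replicate at a stage.

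Whether slopes differed between HM and HZ was tested directly. No gene passed in edgeR (0 of 16207, with 1232 at an unadjusted p under 0.05), DESeq2 called 171, and limma called 0 on log2 CPM and 0 on log2 TPM. The test recovered none of the changes set in simulated counts, but across the HM stages those were smaller than their named sizes. What size of difference in slope 8 pools could detect is therefore not known. Without HM at 24 somites edgeR called 9 genes, and without HM at 15 somites 2.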

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

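The tests of other splits of the pools, of cell make-up, of scaling and of the sources of reads in this part were all chosen after the result they address was seen. The tests of spilled reads use 30 genes with at least 100 CPM in endocrine-like cells of HZ and Ngn3Cre and at least 5 times the level of the other cells of these genotypes, chosen without HM cells. The fold was lowered from 10, which no gene met, before the tests were run. The rule for a sample far from the others was fixed before the data were examined. It was applied to 24 groups of pools, and chance alone marks about 1 in 20 such groups.

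Ptf1a, a transcription factor of pancreatic progenitors, reached 2.963 CPM (without scaling, 89 reads) in the HZ pool of 24 somites, far from the 0 to 0.109 CPM of the other 3 HZ pools tested. It was marked because the gap to the nearest pool was most of the whole range. Such a gap in 1 of 24 groups is no more than chance gives, and no explanation was tested.

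The pool of Ngn3Cre at 18 somites, left out of the tests for its 3 cells, had 855.4 CPM of Neurog3 (260 reads, 755 to 966 CPM from counting error alone). The 5 HZ pools had 81.1 to 133 CPM, and the other Ngn3Cre pools 557 CPM at 21, 153 CPM at 24 and 201 CPM at 27 somites. It was marked as a signal in cells that no comparison used. With 3 cells and no other pool of that genotype and stage, nothing further was tested.

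For HM against HZ, 1 of the 35 splits of the 8 pools into 4 and 4, the real one, called as many as 271 genes, and the highest of the others called 89. Whether chance in how the pools were grouped could give that count stays open, since few of these splits are balanced over stages. For Ngn3Cre against HZ, again 1 of 35 splits, the real one, called as many as 62 genes, and the highest other called 47. These splits also move pools across stages. In each comparison 8 of the 35 keep 1 pool on each side at each shared stage, which is too few for a share under 0.05. For the difference in slope between HM and HZ, the real split called 0 genes, so all 35 splits call at least as many whatever the data (the highest other called 3), and this says nothing about chance.

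The first pattern weighed is the fall of 254 genes in HM. A shift of scale from a few abundant genes is argued against, since the median log2 fold change of all tested genes with library totals alone was -0.103, beside -3.33 for the fallen genes. A low number of endocrine-like cells in HM may account for a part. Without the clusters with endocrine or neural markers, 46.35% of the median log2 difference over the shared stages remained (-0.95 in place of -2.04). That test leaves out both kinds of cluster at once. With only the clusters with neural markers left out, 472 genes fell in place of 254. Of the 271 genes called with all cells, 267 were called again in the same direction. This argues against a low number of neural cells as the source of those calls, though the sizes of the falls were not compared. The 46.35% lies close to the bound of 50% set for the test. The genes were chosen for falls in pools that include the remaining cells, so what remains does not show a change beyond composition, and whether composition is the whole cause stays open. Whether the loss of Neurog3 or the sort set that composition stays open, since the genotype is the difference the design names and embryos and gates are not given.

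The second pattern is the Neurog3 reads in HM. Spill of reads from the other pools stays open. If it brought the 1003 Neurog3 reads, it would bring at least a set number of reads of each of the 30 genes, and these had a median of 6.106 times that number (1.94 to 7.53), with 4 of 30 below it. Reads that HM cells make themselves cannot be told apart from spilled ones here. HM cells that carry another genotype were tested by the share of reads in endocrine-like clusters, where 2 HM cells held 1.553% of the Neurog3 reads. With so few HM cells in that class a low share was likely in advance. HZ cells outside it also had Neurog3, at 137 CPM in 61 pancreatic progenitor-like cells, so that share cannot decide. The 5 HM cells with the most reads held 17.6% of them, and 108 of 171 HM cells had a read. This argues against a few cells of another genotype as the main source, and whether many HM cells carry one stays open. A candidate explanation is transcription from the GFP alleles that keeps a part of the Neurog3 sequence. It was not tested, because counts per gene give no position of reads and the alleles' sequence is not given.

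The third pattern is Neurod1 in the HM pool of 24 somites. Cells of clusters with neural markers held 99.12% of its 10476 Neurod1 reads in 11 of the 80 cells (13.8%). Of its Neurod1 reads, 39.5% lay in 4 neural or neural crest-like cells and 59.6% in 7 cells of an unnamed cluster. These 11 cells also held 97.9% of its reads of the neuronal tubulin Tubb3, but Tubb3 is a marker by which both clusters were picked, so this adds no support. Spill from the other pools as a whole is argued against, since the 30 genes had a median of 0.2066 times the fewest reads it would bring (0.0806 to 0.440), with 28 of 30 below that number. Whether the cells of the unnamed cluster are neural stays open. Its detected neural markers were Tubb3, Elavl3, Elavl4 and Stmn2, and endocrine-like cells also averaged 616 CPM of Tubb3. Both clusters were picked on markers alone, and an EpCAM gate would be set against neural cells.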

How the results depend on the processing

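Alternatives that used library totals alone, cells of at least 100000 reads, cells without certain clusters or only of endocrine-like clusters, or only stages with both genotypes were chosen after the data were seen. No paired analysis was possible because the cell numbers shared between groups name single cells, and no pairing is given beyond the stage, which the genotype fits hold as a factor. Unless a reason is given, the cause was not tested.

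For HM against HZ (17 genes higher and 254 lower), counts of higher and lower genes were 314 and 1072 with DESeq2, 0 and 37 with pools of at least 3 cells, and 32 higher with pools of at least 20 cells. They were 110 and 61 with limma on means of log2(CPM + 1) and 74 and 36 on log2(TPM + 1), so most calls were then higher. They were 0 and 50 with 10 cells drawn per pool, 1 and 135 with somites as a number, 3 and 91 with only the 2 genotypes (2 residual degrees of freedom in place of 4), 2 and 143 with shared stages, 0 and 7 without clusters with endocrine or neural markers (692 genes at an unadjusted p under 0.05 in edgeR), and 54 and 472 without clusters with neural markers. With a pool left out they ranged from 0 to 31 and from 88 to 294.

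For Ngn3Cre against HZ (1 and 61), they were 216 and 704 with DESeq2, 6 and 99 with no filter, 0 and 2 with pools of at least 3 cells, 0 and 0 with limma on log2(CPM + 1) (1741 genes at an unadjusted p under 0.05) and on log2(TPM + 1) (1714), 0 and 17 with 10 cells drawn, 0 and 22 with somites as a number, 0 and 0 in endocrine-like cells (762 in edgeR), and 29 and 249 without clusters with neural markers. Higher genes were 2 with DESeq2 scaling or library totals, 3 with pools of at least 20 cells or cells of at least 100000 reads, and 22 with only the 2 genotypes. With a pool left out they ranged from 0 to 11 and from 0 to 103.

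For the stage trend (0), calls were 305 with DESeq2, 76 with pools of at least 3 cells, 52 with at least 20, 1 with limma on either unit and 3 without HM pools, and 0 to 2 with a pool left out. For the difference in slope (0) they were 171 with DESeq2 and 0 to 9 with a pool left out. With an estimated correlation, camera called 0 lists in place of 10 (HM against HZ), 11 (Ngn3Cre against HZ) and 6 (trend), with smallest adjusted p of 0.176, 0.331 and 0.300. Other alternatives kept these counts within 1.5 times.

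At 24 somites and 50 CPM, Neurog3 was in 0% of HM (up to 3.75%), 30.6% of HZ and 23.9% of Ngn3Cre cells. Neurod1 was then in 15.0% of HM, 62.4% of HZ and 83.2% of Ngn3Cre cells, and Gcg in 6.25% of HM, 38.8% of HZ and 84.5% of Ngn3Cre cells. Thinned to 100000 reads, Neurog3 was in 44.1% of Ngn3Cre cells. The endocrine-like share at 21 and 24 somites was 59.8% (Ngn3Cre) and 38.0% (HZ) at resolution 0.5, 57.9% and 23.9% with TPM, and 56.0% in HZ with 1000 variable genes. Depth limits shares, since 10 CPM is under 1 read in the 117 cells under 100000 reads.

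For HM against HZ, 588 of 862 values of the 32 called genes kept direction and call, 271 kept direction only and 3 reversed. Of 270 values of the 10 landmarks not called, 23 passed and 8 reversed. For Ngn3Cre these were 240, 123 and 1 of 364 values of 14 called genes, and 6 and 10 of 285 of 11 landmarks, and for the trend 2 and 18 of 262 of 11 landmarks. In HM against HZ the reversed values were, with 10 cells drawn, -0.13 for Fxyd2, -0.40 for Pdx1 and 0.0086 for Foxd3. Without clusters with endocrine or neural markers, a filter that also left out a pancreatic progenitor-like cluster, they were 0.070 for Dll4, 0.60 for Fev, 1.07 for Chga, -0.12 for Pdx1, -0.46 for Sox9 and -0.0016 for Hes1. Epcam was at -0.075 and -0.12 with limma on CPM and TPM.

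In Ngn3Cre against HZ they were, in endocrine-like cells, 0.51 for Cdx2 and 0.25 for Hes1. Neurod1 was at -1.39 without Ngn3Cre at 21 and -0.09 without HZ at 24 somites, in a range up to 1.11. Ptf1a was at 0.71 and 0.39 without Ngn3Cre at 24 and 27, 1.83 and 0.40 without HZ at 24 and 27, and 0.50 without clusters with neural markers, with -3.46 as the lowest value with a pool left out. Epcam was at 0.10 with pools of at least 3 cells and 0.069 without Ngn3Cre at 24, in a range from -0.27. In the trend, slopes were -0.070 for Neurod1 without clusters with neural markers and 0.023 for Fev without HM pools. Ghrl was at -0.020 and -0.012 with limma on CPM and TPM, -0.031 without Ngn3Cre pools, and -0.017, -0.028, -0.086 and -0.030 without Ngn3Cre at 21, Ngn3Cre at 27, HZ at 18 and HZ at 24, in a range up to 0.065. Pdx1 was at 0.012 with pools of at least 20 cells, 0.046 with 10 cells drawn, 0.037 without clusters with neural markers, 0.0042 without Ngn3Cre pools, and 0.0043, 0.0032, 0.00070 and 0.0038 without Ngn3Cre at 21, HM at 21, HZ at 18 and HZ at 27, in a range from -0.024. Sox9 was at 0.0061 without HZ at 27.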

Other observations

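The tests in this part were chosen after the data were seen.

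In pancreatic progenitor-like cells Neurog3 was at 10 CPM or more in 46.3% of HM cells (25 of 54) and 55.7% of HZ cells (34 of 61). At 50 CPM these were 0 of 54 HM cells, which allows a share of up to 5.56%, and 34.4% of HZ cells. Mean levels were 11.2 CPM in HM, 137 CPM in HZ and 172 CPM in the 12 Ngn3Cre cells of that class (SD over cells 11.1, 252 and 325).

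In pools of endocrine-like cells alone, the medians of lists that parted Ngn3Cre from HZ were nearer 0. Genes of G2 and M phase had a median log2 fold change of -0.39 in place of -2.01, with 20 of 22 negative and 0 at an unadjusted p under 0.05 in edgeR, and no other tool was run on these pools. Hormones had a median of 1.01 in place of 1.97, with 4 of 13 at an unadjusted p under 0.05, endocrine transcription factors 0.23 in place of 0.92, with 3 of 24, and hormone processing genes 0.28 in place of 1.09, with 6 of 22. These are not pools of like cells, since the alpha cell-like cluster, with Gcg and Pcsk2 among its leading genes, held 77 Ngn3Cre and 15 HZ cells, and the other 3 endocrine-like clusters 54 and 37, 65 and 49, and 36 and 32. These fits had 2 residual degrees of freedom, and edgeR called 0 genes with 762 at an unadjusted p under 0.05.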
